A study of Mus musculus with 13 samples.

How the data were processed

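RNA of whole mouse esophagus was measured by RNA sequencing in 13 libraries, 6 from wild-type (WT) and 7 from dblGATA mice. All animals had received the carcinogen 4-nitroquinoline 1-oxide (4-NQO) for 8 weeks and then its vehicle, propylene glycol, for 8 weeks, a stage that the labels call pre-cancer. Per the labels' protocols, tissue was kept in an RNA preservative, homogenised, extracted with phenol and chloroform, cleaned on columns with DNase digestion, and had a mean RNA integrity number of 8.8. Libraries were stranded and selected for poly-A RNA, per the labels' protocols.

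The main table deposited by the authors held whole numbers per gene and library, treated here as estimated counts that had been rounded before deposit. That reading was inferred from the values: the ratio of the raw to the authors' normalized signal varied by gene and library, as DESeq2 gives when average transcript lengths enter its factors. Of 13122 genes with at least 100 counts in every library, 25.8% had a factor over 10% away from their library's median in at least 1 library. A second table deposited by the authors held that normalized signal, and it served for this check and for an alternative. DESeq2 1.34.0 is named in the submitters' processing notes. The aligner, the counter and the genome build are not given in the sources used here, so no coordinates are printed. The deposited log2 fold changes, test scores and p-values of the authors' comparison were read as the authors' own values. A deposited pathway table held -log10 p-values and z scores, from Ingenuity Pathway Analysis per the file headers. Those values were used only for description.

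The table held 20054 genes, each with a symbol and an identifier, and 28 symbols stood for more than 1 identifier. No column of per-sample values was left unused. Counts summed to between 66.3 and 98.2 per library in units of 1e+06 counts, and a floor of 3 counts was worth 0.0306 to 0.0452 CPM (counts per 1e+06 counts). Such floors cover counting error only. Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 16599. Library sizes were scaled by TMM, and edgeR 4.0.16 was run under R 4.3.3 with robust quasi-likelihood fits (glmQLFit and glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A fold change of at least 1.5 was counted separately. Levels are CPM after TMM, as mean ± SD, and the standard error (SE) of a log2 fold change was the fold change divided by the root of its F statistic. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may in part be technical. No 2 libraries of a group were alike within sampling noise, with a chi-square per degree of freedom of at least 58.4.

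Gene lists were fixed before the data were examined. They covered eosinophils, type 2 cytokines and eosinophil chemoattractants, mast cells and basophils, erythroid cells and platelets, neutrophils, T cells, cytotoxic and NK cells, B and plasma cells, macrophages and dendritic cells, MHC class II, interferon response, inflammatory cytokines and chemokines, basal epithelium, squamous differentiation, hyperproliferative keratinocytes, cell cycle, p53 and DNA damage, NRF2 and xenobiotic metabolism, fibroblasts and extracellular matrix, matrix proteases and mesenchymal transition, skeletal muscle, smooth muscle, adipocytes, endothelium, nerve and Schwann cells, thyroid, airway epithelium and gland, gastric tissue, and immediate early and heat shock genes. Each of these was tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided), with adjustment over the lists. Camera with an estimated correlation and fry stood beside it. A list score is the mean log2 CPM of its tested members, and scores were compared by exact two-sided permutation over all 1716 splits into 6 and 7 libraries. Genes next to Gata1 on the X chromosome formed a further list, which was counted but not tested with camera. Pan-epithelial and blood-forming lists were added after the data had been seen, as were the gene sets of the closing observations, of which 1 gene is not reported here.

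The text names genes by a rule fixed before the data were examined. It takes the 10 largest called changes per direction with a mean of at least 1 CPM in the higher group, leaving out predicted genes and pseudogenes. It also takes 5 genes that check the genotype, Xist, Ddx3y, Nnt and H2-Ea, up to 6 called members per list (or up to 3 not called, of which adipocyte genes are printed with fold changes and Tg and Muc5b with levels), and the 5 smallest p-values per direction in the authors' tables. Il5ra, Alox15, Ear2, Rn18s, Pth, Alb, Ngp and Slc4a1 are named outside this rule, as are genes of the closing observations. H2-Ea was not matched in the table.

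Alternatives fixed beforehand were DESeq2 1.42.0 and limma-voom, other size factors, other filters, the replicate number as a block, a skeletal muscle score or Xist as a covariate, genes of other tissues or sex-linked genes left out, and each library left out in turn. Alternatives chosen after seeing the data were the authors' factors as offsets, libraries with signs of other tissue or of ribosomal RNA left out, Rn18s as a covariate, and ribosomal and small non-coding RNA genes left out. The edgeR fit was tested on simulated data for the dblGATA and WT comparison, drawn from the real means, spreads and library sizes with 200 genes changed among 16549 tested. It recovered 70.4% of the genes changed 1.5-fold, 91.4% of those changed 2-fold and 100% of those changed 4-fold, and called 6 of 16349 unchanged genes. The changed genes were taken among those of at least 1 CPM. Each gene was drawn independently, without shifts shared between genes in a library, so these rates need not hold for the real libraries.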

Results

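RNA of the whole esophagus was compared between 6 WT and 7 dblGATA libraries of mice treated with the carcinogen 4-NQO for 8 weeks and with vehicle for another 8 weeks. The dblGATA mice lack a GATA-binding site in the regulatory region of Gata1 that eosinophils need to form. The comparison asks how the carcinogen-treated esophagus differs between these mice and WT mice.

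Ccr3, the receptor for eotaxins on eosinophils, fell in dblGATA from 0.681 ± 0.338 CPM (SD, n = 6) to 0.139 ± 0.116 CPM (SD, n = 7), a log2 fold change of -2.29 ± 0.48 (SE, edgeR adjusted p = 0.0179). The dblGATA 6 library had 0.387 CPM, above WT 4 (0.38) and WT 5 (0.251). Its eosinophil list score (-0.18) lay above those of WT 1, WT 2, WT 4 and WT 5, and its Il5ra, an interleukin-5 receptor chain, stood at 0.708 CPM, above 5 of 6 WT libraries. Alox15, a lipoxygenase of the same list, was at 7.60 to 9.25 CPM in dblGATA 5, dblGATA 6 and dblGATA 7 and at most 4.96 CPM in WT. Siglecf, a surface lectin of eosinophils, had a log2 fold change of -1.23 ± 0.50 (SE) and did not pass the threshold (edgeR adjusted p = 0.106). Prg2, which encodes the eosinophil major basic protein, had a log2 fold change of -4.12 ± 1.29 (SE, edgeR adjusted p = 0.0516). Its level rested on WT 3, with 744 counts against at most 20 in any other library, and without the WT 3 library its log2 fold change was -0.27. Epx, the eosinophil peroxidase gene, had 142 counts in WT 3 and at most 2 elsewhere, and Gata1 had 106 counts in WT 3 and 1 to 10 elsewhere. Neither passed the count filter. Of 6 tested genes of the eosinophil list, only Ccr3 fell, and the list did not pass (median log2 fold change -0.98, camera adjusted p = 0.0642, and adjusted p = 0.917 with an estimated correlation). Adjusted over the list alone, 2 of its genes were lower. Without WT 4 the list had adjusted p = 0.0217, without WT 1 0.0279, without dblGATA 6 0.0299 and without dblGATA 7 0.0468, and it reached 0.186 without dblGATA 4. Without WT 3 and WT 5 it had adjusted p = 0.341 (median -0.46), and without WT 3 to WT 6 0.396 (median -0.01).

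**Figure D1:**
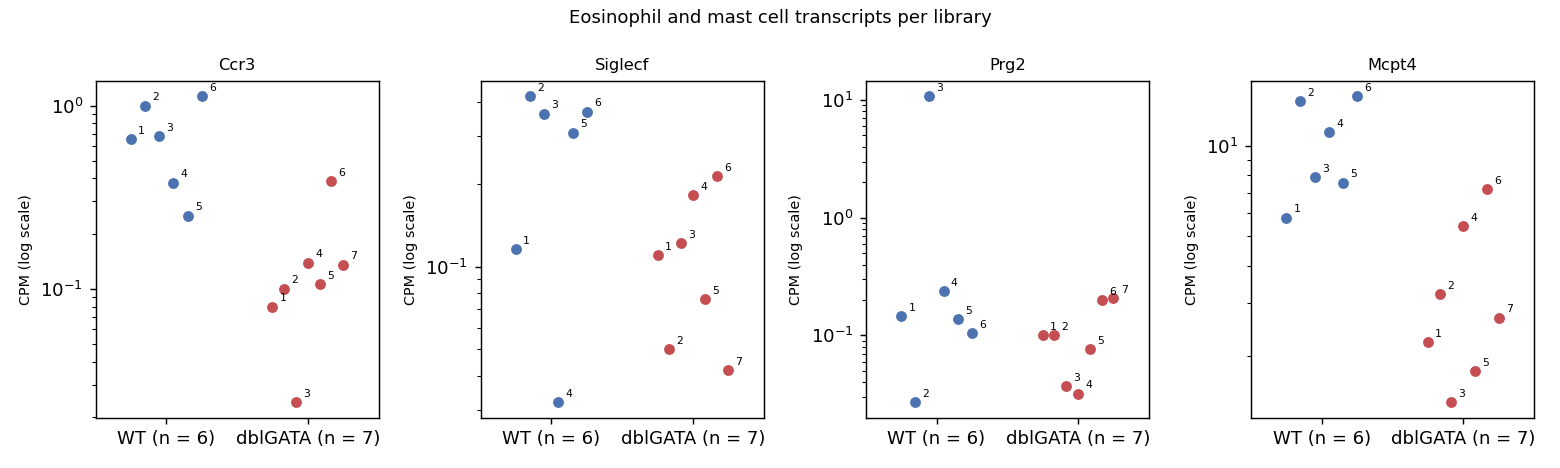
CPM on a log axis for Ccr3, Siglecf, Prg2 and Mcpt4 in 6 WT and 7 dblGATA libraries, each point a library with its replicate number. Ccr3 averages 0.681 in WT and 0.139 in dblGATA, and Prg2 stands at 10.7 in WT 3 against at most 0.238 in the others.

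Basal epithelial and cell cycle genes rose together in dblGATA. Of 9 tested basal epithelium genes, 7 rose and none fell (8 adjusted over the list alone), with a median log2 fold change of 0.61. Of 28 cell cycle genes, 19 rose and none fell (25 adjusted over the list alone), with a median of 0.42. Keratin genes Krt5 and Krt14 rose by log2 fold changes of 0.66 ± 0.13 and 0.88 ± 0.23 (SE, edgeR adjusted p = 0.0174 and 0.0273). Krt5 went from 2041 ± 387 CPM (SD, n = 6) to 3223 ± 509 CPM (SD, n = 7). Trp63, a transcription factor of basal cells, rose by 0.57 ± 0.10 on the log2 scale (SE, edgeR adjusted p = 0.0158). Col17a1, Itga6 and Itgb4, components of the hemidesmosomes that anchor basal cells, rose by 0.76, 0.76 and 0.61 on the log2 scale. Top2a, which untangles DNA in dividing cells, rose by 0.65 ± 0.11 on the log2 scale (SE, edgeR adjusted p = 0.0137), from 71.5 ± 13.1 CPM (SD, n = 6) to 112 ± 8.70 CPM (SD, n = 7). The mitotic genes Aurkb, Cdc20, Ccnb1, Kif11 and Foxm1 rose by 0.44, 0.56, 0.53, 0.53 and 0.46 on the log2 scale. Krt14 lost the call without WT 4, WT 6, dblGATA 5 or dblGATA 7 (highest adjusted p = 0.0645), and the other genes named here kept it whichever library was left out.

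The score of the basal epithelium list was 8.27 ± 0.16 (SD, n = 6) in WT and 8.82 ± 0.16 (SD, n = 7) in dblGATA, and that of the cell cycle list was 4.28 ± 0.17 and 4.70 ± 0.15. For both lists each of the 7 dblGATA libraries lay above all WT libraries (exact permutation p = 0.000583, the smallest that 1716 splits can give, and 0.00292 adjusted over 10 scores). Against other genes, camera gave adjusted p = 1.41e-06 for the basal epithelium list and 7.39e-13 for the cell cycle list. These became adjusted p = 0.556 and 0.717 with an estimated correlation, while fry, which asks whether a list moves one way, gave adjusted p = 0.00153 and 0.00755. Beside this rise the skeletal muscle list was lower by camera (adjusted p = 1.2e-05, and adjusted p = 0.917 with an estimated correlation; score difference -0.55, exact permutation p = 0.0175, 0.0548 adjusted). WT 4 and WT 6 held 10.1% and 16.9% of their counts in Rn18s, a ribosomal RNA gene, against at most 3.24% in any other library.

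**Figure D2:**
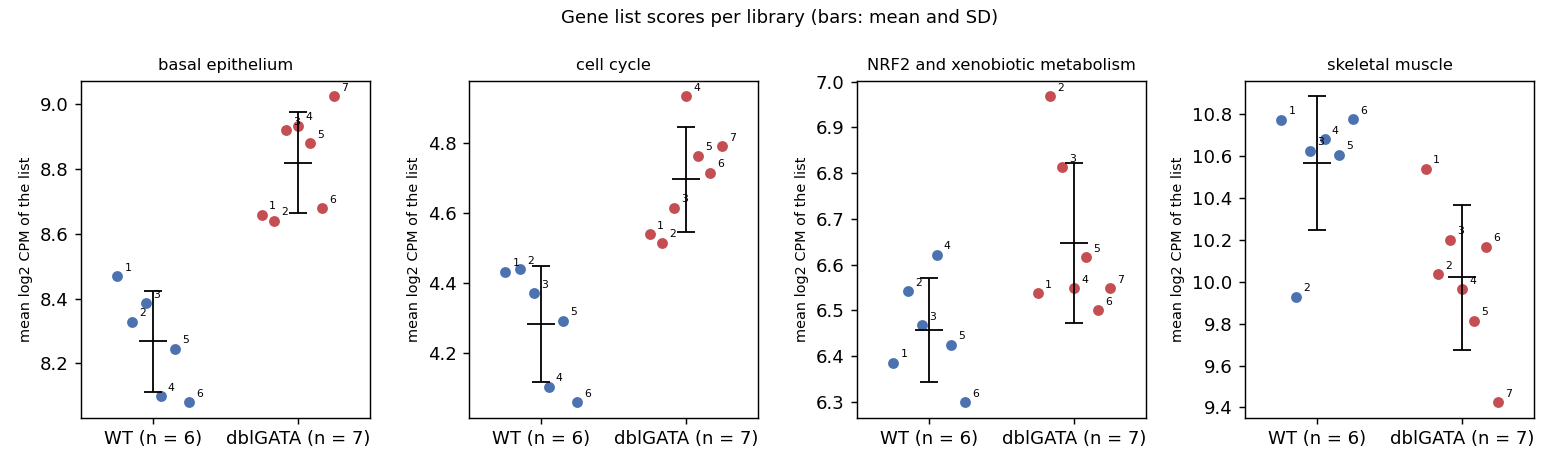
Mean log2 CPM of 4 gene lists in 6 WT and 7 dblGATA libraries, each point a library with its replicate number, with the mean and SD of each group. The basal epithelium and cell cycle scores of all 7 dblGATA libraries lie above those of the WT libraries, and WT 2 has the lowest skeletal muscle score of the WT group (9.93).

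In all, 2239 of 16599 genes changed (edgeR, adjusted p under 0.05), 1179 higher and 1060 lower in dblGATA. At least a 1.5-fold change was met by 279 of them, 72 higher and 207 lower. With upper-quartile scaling the split moved to 830 higher and 1299 lower. The count rested on single libraries: it was 357 without WT 6, 396 without WT 4, 535 without dblGATA 5, 546 without dblGATA 7, 754 without dblGATA 3, 1206 without WT 1 and 3828 without WT 2. No gene passed in edgeR or limma-voom without WT 4 and WT 6, with Rn18s as a covariate, or with the skeletal muscle score as a covariate. In these 3 settings edgeR had 3542, 3912 and 1713 genes at an unadjusted p under 0.05, against 5371 with all libraries, and DESeq2 called 1087, 1537 and 33. The median fold of the 2239 genes was 83.9%, 87.1% and 67.8% of its log2 size with all libraries, and the median SE was 112%, 115% and 125% of its size. Col17a1, at 0.76 ± 0.11 (SE) on the log2 scale with all libraries, was at 0.66 ± 0.11, 0.66 ± 0.12 and 0.61 ± 0.13, and Top2a, at 0.65 ± 0.11, was at 0.49 ± 0.07, 0.49 ± 0.09 and 0.55 ± 0.14.

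Among the 10 largest rises, Fosl1, an AP-1 transcription factor, rose by 1.39 ± 0.39 on the log2 scale (SE, edgeR adjusted p = 0.035), Has3, a hyaluronan synthase, by 1.21 ± 0.25 (0.018), and Krt6a, a keratin of proliferating epithelium, by 1.07 ± 0.29 (0.0326). Lama3, a laminin chain of the epithelial basement membrane, rose by 0.97 ± 0.20 and Bnc1, a zinc-finger factor of basal keratinocytes, by 0.96 ± 0.16 (edgeR adjusted p = 0.0179 and 0.0137). Fmo9, Bhlhe22, Cdhr1 and Akr1d1 had log2 fold changes from 0.93 to 1.11. The symbol Ndor1 stands for 2 features: a minor one rose by 1.38 ± 0.33 on the log2 scale (0.416 CPM in WT), and the main one, at 30.7 CPM in WT, had a log2 fold change of 0.23 ± 0.09 (SE, edgeR adjusted p = 0.0892). Of 61 called genes that were followed, 18 kept the call whichever library was left out, among them Has3, Lama3, Bnc1, Bhlhe22, Col17a1, Itga6, Itgb4, Krt5, Trp63, Top2a, Gclm and Ccr3. Without WT 4, WT 6, dblGATA 5 or dblGATA 7, Fosl1, Ndor1, Fmo9, Krt6a, Cdhr1 and Akr1d1 lost it (highest adjusted p = 0.0837). Dropping dblGATA 3 ended it for Fosl1, Fmo9, Krt6a and Akr1d1, WT 1 for Fosl1, Fmo9 and Akr1d1, WT 3 for Fmo9 and Krt6a, WT 5 for Fosl1 and Krt6a, and dblGATA 4 for Fosl1 and Fmo9.

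Lists of squamous differentiation, hyperproliferative keratinocyte and NRF2 genes were higher in dblGATA by camera. Of 24 squamous differentiation genes 2 rose, Tgm1, a transglutaminase of the cornified envelope (log2 fold change 0.52 ± 0.15, SE), and Sprr1b, an envelope precursor (0.65 ± 0.19). The list had a median of 0.39 and camera adjusted p = 0.00321, and adjusted p = 0.917 with an estimated correlation. Its score differed by 0.31 (exact permutation p = 0.0431, 0.0616 adjusted over 10 scores), as did a pan-epithelial score (0.31, exact permutation p = 0.0274, 0.0548 adjusted), and the difference of these scores was level between the groups (-0.00, exact permutation p = 0.98). Of 13 hyperproliferative keratinocyte genes, Krt6a and Tgfa, an EGF receptor ligand, rose (median 0.54, camera adjusted p = 0.0334, and adjusted p = 0.917 with an estimated correlation). That call was lost without WT 5 (adjusted p = 0.187), WT 3 (0.0794), dblGATA 5 (0.0602), dblGATA 1 (0.0537) or dblGATA 7 (0.0513). It was also lost with the skeletal muscle covariate (median 0.34, adjusted p = 0.405), without WT 3 and WT 5 (0.49, 0.41) and without WT 3 to WT 6 (0.56, 0.286), while the median was 1.03 without WT 4 and WT 6, 1.02 with Rn18s and 0.88 with Xist as a covariate. Of 19 NRF2 and xenobiotic genes, Gclm and Gclc, the subunits of the enzyme that limits glutathione synthesis, rose by 0.60 ± 0.09 and 0.58 ± 0.15 on the log2 scale (SE, edgeR adjusted p = 0.0137 and 0.0269), and Ugt1a6a by 0.36 ± 0.11. Adjusted over the list alone, 8 were higher and 1 lower (median 0.29, camera adjusted p = 0.0102, and adjusted p = 0.917 with an estimated correlation). Adjusted over each list alone, 2 squamous differentiation and 2 hyperproliferative keratinocyte genes were higher. Gclm kept its call whichever library was left out. Without WT 4, WT 6, dblGATA 3 or dblGATA 5, Tgm1, Sprr1b, Tgfa, Krt6a, Gclc and Ugt1a6a lost the call (highest adjusted p = 0.106, Ugt1a6a), and without dblGATA 7 all but Gclc. Dropping WT 5 or WT 1 ended it for Tgm1, Sprr1b, Tgfa and Ugt1a6a (WT 5 also for Krt6a), WT 3 for Sprr1b, Tgfa and Krt6a, and dblGATA 2 for Tgfa and Ugt1a6a.

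The mouse esophagus has a coat of striated muscle, and 4 of 16 listed skeletal muscle genes were lower in dblGATA (9 adjusted over the list alone), with a median log2 fold change of -0.50 (camera adjusted p = 1.2e-05, and adjusted p = 0.917 with an estimated correlation). The score of the list differed by -0.55 (exact permutation p = 0.0175, 0.0548 adjusted over 10 scores), and fry gave adjusted p = 0.135. Myl1, Mylpf, Tnnc2 and Tnni2, genes of the fast-muscle sarcomere, had log2 fold changes of -0.59, -0.60, -0.56 and -0.53, with edgeR adjusted p from 0.0257 to 0.035. Myl1 went from 1283 ± 220 CPM (SD, n = 6) to 850 ± 191 CPM (SD, n = 7). Of 10 smooth muscle genes, Des, the muscle intermediate filament desmin, fell by 0.54 ± 0.15 on the log2 scale (SE, edgeR adjusted p = 0.0332). The adipocyte list was lower by camera (median -0.82, adjusted p = 0.0122, and adjusted p = 0.917 with an estimated correlation), although none of its 10 genes passed. Fabp4 and Adipoq had log2 fold changes of -0.83 ± 0.32 and -0.96 ± 0.41 (SE, edgeR adjusted p = 0.0966 and 0.131), and without WT 5 the list had camera adjusted p = 0.0967. Without WT 4, WT 6, dblGATA 3, dblGATA 5 or dblGATA 7 the 4 skeletal muscle genes and Des lost the call (highest adjusted p = 0.086), and without WT 1 all but Myl1. Dropping dblGATA 2 ended it for Tnnc2, Tnni2 and Des, and dblGATA 4 for Tnnc2 and Tnni2.

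Immune transcripts changed in few genes. Mcpt4, a mast cell protease, fell from 10.2 ± 3.68 CPM (SD, n = 6) to 3.42 ± 2.12 CPM (SD, n = 7), a log2 fold change of -1.57 ± 0.37 (SE, edgeR adjusted p = 0.0231). Ms4a2, a chain of the IgE receptor, rose by 0.66 ± 0.19 on the log2 scale (SE, edgeR adjusted p = 0.0366), and the other 12 tested mast cell and basophil genes did not pass. Foxp3, the factor of regulatory T cells, rose by 0.83 ± 0.25 on the log2 scale (SE, edgeR adjusted p = 0.0395), as the only one of 13 T cell genes. The T cell list had a median of 0.41 (camera adjusted p = 0.00942, and adjusted p = 0.917 with an estimated correlation), and a median of 0.30 (adjusted p = 0.0779) without WT 3 and WT 5. With the skeletal muscle covariate its median was 0.22 (0.235), with Rn18s 0.25 (0.0706), without WT 4 and WT 6 0.21 (0.0428) and without WT 3 to WT 6 -0.01 (0.953). Of the neutrophil genes, Retnlg fell by 3.10 ± 0.79 and Il1r2 rose by 0.34 ± 0.09 on the log2 scale (SE, edgeR adjusted p = 0.0272 and 0.0279). Retnlg stood at 4.99 CPM in WT 3, the library with abundant eosinophil granule transcripts, and at 0.218 to 0.842 CPM in the other WT libraries, and without WT 3 its log2 fold change was -1.79 (adjusted p = 0.0506). Without WT 6, dblGATA 5 or dblGATA 7 each of these genes lost the call, Mcpt4 with adjusted p up to 0.0593 and Foxp3 up to 0.0832. Dropping WT 4 ended it for all but Retnlg, dblGATA 3 for Foxp3, Retnlg and Il1r2, WT 3 for Foxp3 and Retnlg, WT 5, dblGATA 2 or dblGATA 4 for Ms4a2 and Foxp3, and WT 1 or dblGATA 6 for Ms4a2. Ccl3, a chemokine at 0.117 ± 0.0493 CPM (SD, n = 6) in WT, rose by 1.01 ± 0.30 on the log2 scale (SE, edgeR adjusted p = 0.0411), a call held only without WT 1, WT 2 or dblGATA 2 among the fits without 1 library (adjusted p up to 0.0951 in the others). No gene passed in the lists of type 2 cytokines, erythroid cells and platelets, cytotoxic and NK cells, B and plasma cells, macrophages and dendritic cells, MHC class II or interferon response, and none of these lists passed with all libraries (camera adjusted p from 0.198 to 0.797). The cytotoxic and NK list had adjusted p = 0.0302 without dblGATA 3, and the interferon response list 0.043 without dblGATA 2.

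In the remaining lists few genes passed, and no list did with all libraries. Of 18 p53 and DNA damage genes, Plk2 rose by 0.41 ± 0.10 and Ccng1 fell by 0.39 ± 0.11 on the log2 scale (camera adjusted p = 0.969). Among matrix protease and mesenchymal transition genes, Mmp14, Plau and Snai2 rose by 0.26, 0.52 and 0.51 on the log2 scale (camera adjusted p = 0.63), and among immediate early and heat shock genes Junb, Ier2 and Dnajb1 rose by 0.41, 0.29 and 0.33 (0.14). S100b, a Schwann cell gene, had a log2 fold change of -0.78 ± 0.24 (SE, edgeR adjusted p = 0.0473, list adjusted p = 0.485). Fibroblast (adjusted p = 0.987), endothelium (0.35), smooth muscle (0.178), inflammatory cytokine (0.178), mast cell (0.969) and neutrophil (0.969) lists did not pass either. Without 1 library the immediate early list had adjusted p = 0.0299 (without dblGATA 6), 0.043 (dblGATA 2) and 0.0451 (WT 1), the smooth muscle list 0.0298 (WT 6 or dblGATA 4) and the inflammatory cytokine list 0.0387 (dblGATA 2). Without WT 4 or WT 6 each called gene of this paragraph lost the call, without dblGATA 5 all but Junb, without dblGATA 7 all but Junb and Plk2, and without dblGATA 3 all but Junb and Mmp14 (highest adjusted p = 0.107, Dnajb1). Dropping WT 1, WT 3, WT 5, dblGATA 1, dblGATA 2 or dblGATA 4 ended it for some of Ccng1, Snai2, Dnajb1 and S100b.

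The largest falls came from transcripts abundant in a few WT libraries. A2ml1 (log2 fold change -6.76) stood at 122 CPM in WT 3 and at most 0.523 elsewhere, Kcnh3 (-5.60) at 48.6 CPM in WT 5 and at most 0.563 elsewhere, and Ager (-4.35) at 71.4 CPM in WT 5 and at most 1.04 elsewhere. Without the library that held them, their log2 fold changes were -0.38, -0.27 and -0.07. Ppp1r1b was highest in WT 5 (37.9 CPM) and WT 3 (14.6 CPM). The non-coding RNAs Rnu1a1, Snord15b, Rn7s1, Rny3 and n-R5s100 had log2 fold changes from -3.83 to -3.41 and were highest in WT 6 and then WT 4. Pcdhgc4, a protocadherin, had a log2 fold change of -3.42 ± 0.69 (SE, edgeR adjusted p = 0.0179), with 30.8 CPM in WT 1, 8.69 to 10.6 in WT 3, WT 4 and WT 6, 0.607 and 1.35 in WT 2 and WT 5, and a mean of 0.960 ± 0.192 CPM (SD, n = 7) in dblGATA. Its call held whichever library was left out, while the other 9 lost theirs without WT 6, dblGATA 3, dblGATA 5, dblGATA 7 or WT 4, and A2ml1, Kcnh3, Ager, Ppp1r1b and n-R5s100 without 4 or more others as well.

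Transcripts of other tissues were abundant in some libraries of both groups. WT 5 held 1247501 counts of Tg, the thyroid hormone precursor, and 76956 counts of Pth, the parathyroid hormone. The dblGATA 1 and dblGATA 4 libraries held 10771 and 4551 counts of Tg. WT 3 held 313201 counts of Muc5b, a mucin of glands, dblGATA 6 held 1553 and WT 4 held 1004, and dblGATA 5 held 12942 counts of Alb, the liver albumin gene. The thyroid (camera adjusted p = 0.373), airway and gland (0.634) and gastric (0.696) lists did not differ detectably between the groups. On the first principal component of the 500 most variable genes (26.8% of variance) WT 3 and WT 5 stood apart, at 48.2 and 29.7. Xist and Y-linked transcripts occurred together in 6 libraries. Nnt, which differs between C57BL/6 substrains, was at 20.6 ± 5.28 CPM (SD, n = 6) and 18.6 ± 3.78 CPM (SD, n = 7; edgeR adjusted p = 0.598). A second feature of that symbol, which did not pass the count filter, was at 4.23, 3.79, 7.61 and 5.51 CPM in WT 1, WT 2, WT 6 and dblGATA 2 and at 0 in the other 9 libraries. The labels give C57/BL6 as the strain of the WT mice, and how the dblGATA line was bred is not given in the sources used here. Of 22 tested genes next to Gata1 on the X chromosome, Timm17b fell by 0.21 ± 0.05 and Gpkow rose by 0.23 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 0.028 and 0.0282), and 5 were higher and 1 lower adjusted over the list alone (median 0.09). Both genes lost the call without WT 4, WT 6, dblGATA 3, dblGATA 5 or dblGATA 7, and Gpkow also without WT 1 (highest adjusted p = 0.07).

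**Figure D3:**
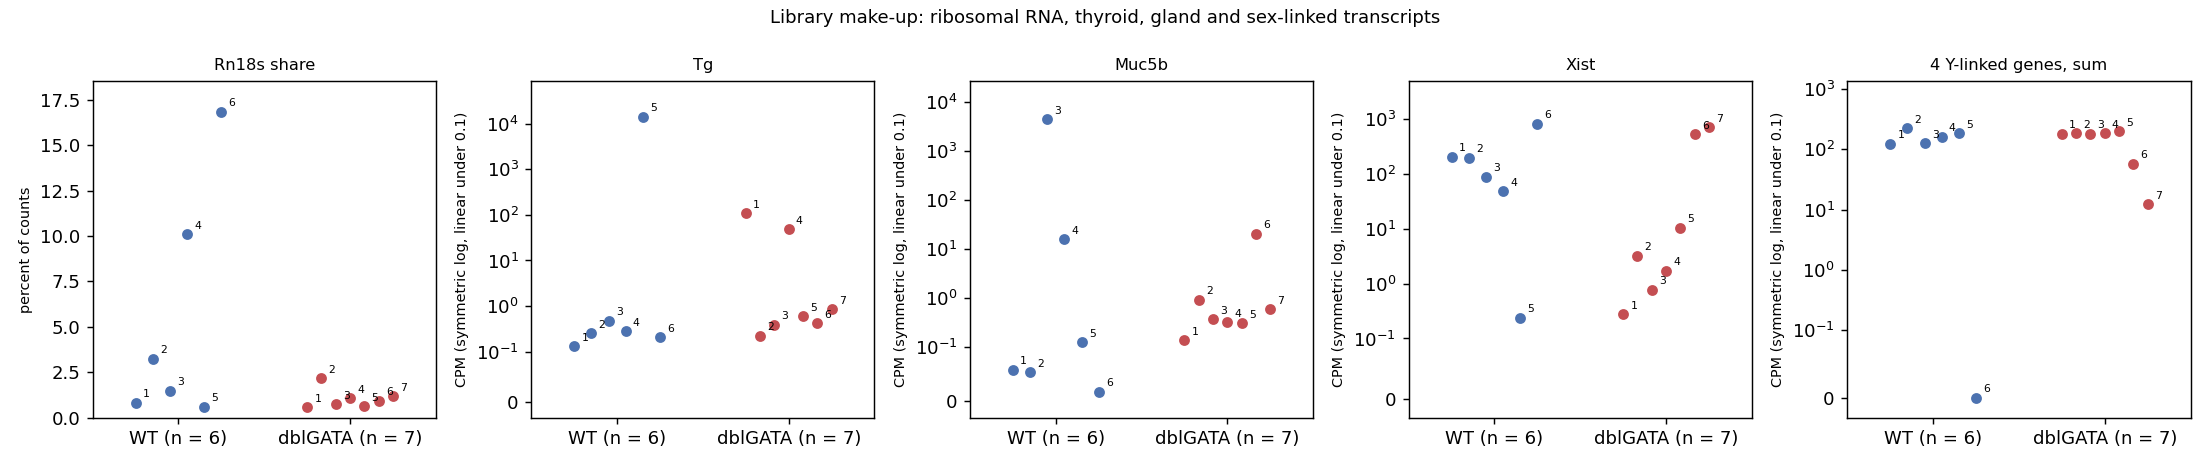
Share of Rn18s in all counts (percent), and CPM of Tg, Muc5b, Xist and the sum of 4 Y-linked genes on symmetric log axes, in 6 WT and 7 dblGATA libraries, each point a library with its replicate number. WT 6 has 16.9% Rn18s and no Y-linked counts, WT 5 has 14232 CPM of Tg and WT 3 has 4519 CPM of Muc5b.

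The authors' deposited table called 3110 genes at an adjusted p under 0.05, 1635 higher and 1475 lower, and 1996 of them were also called here. In the authors' deposited table the smallest p-values among higher genes belonged to Kcnh1, Dsc3, Gtse1, Gclm and Golim4, with log2 fold changes from 0.45 to 0.78. Among lower genes of the authors' deposited table they belonged to Pcdhgc4 (-4.42), Mcrip2, Zic1, Cox8b and Nme3. Of 137 genes in the authors' deposited table of rises of at least 1.5-fold, 130 were tested here, all higher, and 83 were called. Of 155 in the authors' deposited table of falls to at most a fold of 0.5, 105 were tested here, all lower, and 50 were called. The same libraries underlie both, so this compares tools only. In the authors' deposited table of pathways, Mitochondrial Dysfunction (z = 6.83) and Oxidative Phosphorylation (z = -8.31) had the smallest p-values with a positive and a negative z score. The next in that table were Sirtuin Signaling (z = 4.13), Estrogen Receptor Signaling, Granzyme A Signaling and Senescence with a positive score. With a negative score they were the G2/M DNA damage checkpoint, neutrophil extracellular traps, adipogenesis and RHOGDI signaling.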

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

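The tests on WT 3, on sex-linked transcripts, on the cell cycle score against the pan-epithelial score, on list scores with the muscle covariate, and without WT 4 and WT 6 were chosen after the result was seen. The pan-epithelial list was added after the data had been seen, so the basal epithelium test against it came later too. In 198 groups of libraries tested for a single library far from the rest, 15 stood out, where chance alone gives about 9.9.

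A higher share of epithelium against muscle in dblGATA would leave the basal epithelium score level with the pan-epithelial score of the same library. The difference was larger in dblGATA by 0.24 (exact permutation p = 0.0396, 0.0616 adjusted over 10 scores), past the threshold only before adjustment. A pan-epithelial score that follows the epithelial share only in part would give such a difference too, so this test does not decide against the share. For the cell cycle list the difference from the pan-epithelial score was larger in dblGATA by 0.10 (exact permutation p = 0.46), which lies within the spread between libraries. A larger epithelial share and more dividing cells therefore cannot be told apart. The cell cycle score minus the basal epithelium score differed by -0.139 (exact permutation p = 0.0227, 0.0548 adjusted over 10 scores), so the cell cycle score rose no more than the basal epithelium score. The basal epithelium score minus the squamous differentiation score differed by 0.245 (exact permutation p = 0.117, 0.146 adjusted). No prediction was set for these differences. With the skeletal muscle score as a covariate the differences between groups were 0.43 ± 0.11 (SE) for the basal epithelium score and 0.28 ± 0.10 for the cell cycle score, against 0.55 ± 0.09 and 0.41 ± 0.09 without it. The muscle score as measured thus left part of both differences. A score that follows the muscle share only in part would do so too, so the share is not argued against. With that covariate edgeR called 0 genes (1713 at an unadjusted p under 0.05, 33 called by DESeq2, 0 by limma-voom). Without WT 4 and WT 6, a setting chosen after the result was seen, the cell cycle median was 0.31, 74.4% of its size. That lies between the bounds set for this test, so extra non-polyadenylated RNA in these libraries stays open as part of the cause. With Xist as a covariate the median was 0.418, which argues against the mean Xist level as the cause. Xist averaged 228 ± 305 CPM (SD, n = 6) in WT and 179 ± 305 CPM (SD, n = 7) in dblGATA, so this covariate could move the median little. Xist and Y-linked transcripts occurred together in 4 WT and 2 dblGATA libraries, and whether that matters for the list was not tested. A lack of eosinophils in dblGATA remains an untested hypothesis beside the open explanations. Ccr3 was lower in dblGATA but not absent, with 80 counts over its libraries.

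The eosinophil granule transcripts Prg2 and Epx were abundant in WT 3 alone, where log2 CPM of Prg2 was 3.43 against -1.92 in the next WT library. Ear2, a ribonuclease of the eosinophil list, was at 2.77 CPM in WT 3 and higher in WT 6 (4.72 CPM) and dblGATA 6 (3.20 CPM). Blood-forming tissue carried into WT 3 is a candidate explanation: all 17 listed genes of blood-forming tissue found were highest in WT 3, with a median log2 ratio of 4.94 to the other libraries, led by Ngp (37.7 CPM) and Slc4a1 (35.0 CPM). Of the 18 genes in that list, 6 are also in other lists. More mature eosinophils in WT 3 were argued against by Ccr3 and Siglecf, which had log2 ratios of WT 3 to the median of the other WT libraries of 0.05 and 0.20 (SD of the others 0.84 and 1.07), far below the 5.85 of Prg2.

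Xist and Y-linked transcripts occurred together in WT 1 to WT 4, dblGATA 6 and dblGATA 7. RNA from animals of both sexes in 1 library may account for this. The Xist share of the WT 6 level and the Y-linked share of the male level were summed. The sum was 0.79 to 0.95 in 5 of 6 such libraries, below the 1 that a mixture gives, and 1.45 in WT 2. In WT 2 the Y-linked level was 121.1% of the male level beside Xist at 23.8%, which a mixture alone does not give. The Y-linked share had an SD of 3.5% over the 6 libraries at the male level. Reads assigned to the wrong library were argued against, for reads spread over all libraries, since Tg, at 14232 CPM in WT 5, reached at most 0.0059% of that level in the 6 libraries with both and in WT 6, and WT 6 had no Y-linked counts. The dblGATA 1 and dblGATA 4 libraries, which have Xist at the male level, held 0.75% and 0.34% of that Tg level, together with counts of Pth. Among the WT libraries log2 CPM of Xist was lowest in WT 5 (-1.91, next WT library 5.61), and log2 CPM of Ddx3y was lowest in WT 6 (-5.28, next WT library 5.61). No biological explanation was tested.

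The count of changed genes was compared with 100 of the 1716 splits of the libraries into 6 and 7. As many genes as the real 2239 were reached in 2 splits, the real one included, a share under the bound set beforehand. This argues against chance without excluding it, since the highest other split gave 3334, more than the real one. That split exchanged WT 2 with dblGATA 1, and 98 splits gave 0. This points to a structure of the samples in which WT 2 lies toward the dblGATA group, dblGATA 1 toward WT, or both. A single split cannot separate these, and edgeR called 3828 genes without WT 2 and 2851 without dblGATA 1.

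Single libraries far from the rest of their group were as follows. WT 5 had the highest thyroid score (5.35, next 0.03), log2 CPM of Ager (6.16) and log2 CPM of Kcnh3 (5.60). WT 3 had the highest airway and gland score (6.09), matrix protease score (3.89) and log2 CPM of A2ml1 (6.93). WT 2 had the lowest skeletal muscle score (9.93, next 10.61). In dblGATA, library 2 had the lowest neutrophil score (2.05, next 3.52) and the highest Rn18s share (2.17%), library 6 the highest airway and gland score (1.5), library 4 the highest log2 CPM of Lama3 (6.95) and library 7 that of Foxp3 (2.71).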

How the results depend on the processing

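The settings without WT 3 and WT 5, without WT 4 and WT 6, without all 4, with Rn18s as a covariate, with the authors' factors as offsets and without ribosomal and small non-coding RNA genes were chosen after the result was seen. Limma-voom called 2008 genes, RLE scaling 2180, no count filter 1947, a filter at 1 CPM 2411, tissue lists left out 2248, Xist as a covariate 1980, sex-linked genes left out 2252, the authors' factors 1899, WT 3 and WT 5 left out 2218, and ribosomal and small non-coding RNA genes left out 2205, each within 1.5 times of 2239. Of the 2239 genes, 1529 were still called without WT 3 and WT 5, 1666 with the authors' factors, and 1897 to 2239 in the other settings just named. DESeq2 called 3603 (1816 higher, 1787 lower, 458 at least 1.5-fold). With the skeletal muscle score as a covariate, with Rn18s as a covariate, without WT 4 and WT 6, and without WT 3 to WT 6, edgeR called 0 genes in either direction and 0 at least 1.5-fold, and limma-voom 0. Without WT 3 to WT 6 edgeR had 2707 genes at an unadjusted p under 0.05 and DESeq2 called 873. The fit without WT 3 and WT 5, of the same size as that without WT 4 and WT 6, called 2218 genes. The fit without WT 4 and WT 6 kept WT 3 and WT 5, which stood apart on the first principal component. These fits therefore differ in more than size and cannot show whether fewer libraries account for the 0. The cause was not tested. With all libraries the adjusted p-values were crowded near the threshold, with a lowest of 0.00596, 388 genes under 0.02 and 3990 under 0.1.

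The groups share replicate numbers, but libraries of the same number did not deviate together (correlations from -0.106 to 0.061, and 0 of 6 WT libraries correlated best with their own number). With the number as a replicate block 868 genes were called (490 higher, 378 lower, 70 at least 1.5-fold).

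Leaving out 1 library moved the changed genes between 357 and 3828, the higher between 222 and 1928, the lower between 135 and 1900, and those of at least 1.5-fold between 45 and 664. Of 61 called genes that were followed, 43 lost the call in at least 1 of these fits, 43 without WT 6, 42 without WT 4, 42 without dblGATA 5, 40 without dblGATA 7 and 36 without dblGATA 3, and none turned direction.

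The basal epithelium, cell cycle, squamous differentiation, NRF2 and skeletal muscle lists passed without any 1 library, with camera adjusted p up to 2.62e-05, 4.26e-11, 0.0231, 0.043 and 8.38e-05. With an estimated correlation no list passed: adjusted p was 0.556 for basal epithelium, 0.717 for cell cycle and 0.917 for T cell, squamous differentiation, hyperproliferative keratinocyte, NRF2, skeletal muscle and adipocyte. With fry it was 0.178 for squamous differentiation, 0.145 for NRF2, 0.135 for skeletal muscle and 0.256 for T cell, hyperproliferative keratinocyte and adipocyte. The eosinophil list passed with no count filter (0.0308), the replicate block (0.0291), the muscle covariate (0.0115), the Xist covariate (0.0482) and without WT 4 and WT 6 (0.0376), but had 0.341 (median -0.46) without WT 3 and WT 5 and 0.396 (median -0.01) without WT 3 to WT 6, against a median of -0.98 with all libraries, and ranged from 0.0217 to 0.186 without 1 library. The hyperproliferative keratinocyte list, with a median of 1.03 without WT 4 and WT 6, 1.02 with Rn18s and 0.88 with Xist, had 0.065 with the replicate block, 0.405 with the muscle covariate, 0.41 without WT 3 and WT 5 and 0.286 without WT 3 to WT 6, and ranged from 0.00129 to 0.187 without 1 library. The T cell list had 0.235 with the muscle covariate, 0.0779 without WT 3 and WT 5, 0.0706 with Rn18s, and 0.953 without WT 3 to WT 6, where its median was -0.01. The adipocyte list had 0.0897 without WT 3 and WT 5, and ranged from 0.000116 to 0.0967 without 1 library. The macrophage and dendritic cell list passed without WT 4 and WT 6 (0.0165), without WT 3 to WT 6 (0.0461) and with Rn18s (0.0201), and the immediate early list with the muscle covariate (0.0361). The skeletal muscle list turned to a median of 0.04 (0.829) with its own score as a covariate, by construction. Without WT 3 to WT 6 the nerve and Schwann cell list turned to 0.72 (0.00412). Where construction does not show it, the cause was not tested.

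Direction turned for these log2 fold changes, none of them past the threshold: without WT 3 and WT 5, Ppp1r1b (0.39), Ager (0.0207), Kcnh3 (0.57) and Nnt (0.0022), the libraries that held the first 3 being left out. Without WT 3 to WT 6 they were Ppp1r1b (0.77), Kcnh3 (0.29), A2ml1 (0.10), Prg2 (0.33), S100b (0.0491), Nnt (0.22) and Ddx3y (-0.43). Xist was at 0.53 without WT 4 and WT 6, 0.97 with Rn18s and 0.73 without WT 6 (-1.33 to 0.73 without 1 library), and Nnt at 0.32 with the muscle covariate. Ddx3y, at 0.00 with all libraries, was at -0.000664 with DESeq2, -0.00346 with RLE, -0.0404 with upper-quartile scaling, -0.00588 at 1 CPM, -0.0927 with the muscle covariate, -0.0831 with Xist, -0.30 without WT 4 and WT 6, -0.35 with Rn18s, -0.0121 without ribosomal and small non-coding RNA genes, and between -0.26 and 0.24 without 1 library. At an adjusted p under 0.1, 113 and 91 genes of the authors' lists of higher and lower genes were called, against 83 and 50.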

Other observations

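The genes in the next 2 paragraphs were chosen after their values were seen. Beyond Col17a1, Itga6 and Itgb4, the laminin genes Lama3 and Lamb3 were higher in dblGATA, by 0.97 ± 0.20 and 0.70 ± 0.17 on the log2 scale (SE, edgeR adjusted p = 0.0179 and 0.0236). Itga3, a laminin receptor, rose by 0.62 ± 0.14. Of 14 hemidesmosome and basement membrane genes reported, 6 rose and none fell (median log2 fold change 0.10), and Plec, Cd151 and Nid1 had log2 fold changes of -0.20 ± 0.07, -0.19 ± 0.08 and -0.15 ± 0.13 (SE, edgeR adjusted p = 0.0681, 0.128 and 0.436). Of 8 hyaluronan genes, Has3, the hyaluronan receptors Cd44 and Hmmr, and the hyaluronidase Hyal1 rose, while Has1 and Has2 had log2 fold changes of 0.20 and -0.10 and did not pass. Of 13 genes of AP-1 and EGF receptor signalling, 5 rose and none fell (median log2 fold change 0.41).

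Of the 13 mRNAs encoded by the mitochondrial genome, 10 fell in dblGATA, with a median log2 fold change of -0.44. COX1 went from 19200 ± 2020 CPM (SD, n = 6) to 14100 ± 1090 CPM (SD, n = 7). Their share of all counts was 5.55 ± 0.665% (SD, n = 6) in WT and 4.39 ± 0.452% (SD, n = 7) in dblGATA (exact permutation p = 0.0035). In the same comparison the skeletal muscle list had a median log2 fold change of -0.50 (camera adjusted p = 1.2e-05, and adjusted p = 0.917 with an estimated correlation). WT 4 and WT 6, with 10.1% and 16.9% of counts in Rn18s, held 5.17% and 4.99% in mitochondrial mRNA, below the WT mean. Among the genes that fell, ND6 was highest in WT 6 and then WT 4 (91.3 and 59.4 CPM). WT 2 had the lowest skeletal muscle score of the WT group (9.93) and 6.05% of counts in mitochondrial mRNA.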
